A study of Mus musculus with 42 samples.

How the data were processed

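Mouse lung mesenchymal cells from 2 strains were profiled by RNA-seq, which counts messenger RNA reads per gene, and by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA. The 42 samples comprised 21 RNA and 21 ATAC libraries. Per the labels, CD1 mice carried a Col1a1-GFP reporter, and GFP-positive cells negative for the leukocyte marker CD45, the epithelial marker EpCAM and the endothelial marker CD31 were sorted from lungs digested for 45 min. They were either collected at once (sham) or cultured for 5 days in medium with 10% serum on collagen-coated silicone gels with a stiffness of 0.2 kPa or 32 kPa. Lineage-traced Col1a2-expressing cells of C57BL/6 mice, negative for CD45 and EpCAM, were sorted after sham treatment and 14 and 56 days after bleomycin, a drug that injures the lung and causes fibrosis. Each CD1 group had 3 libraries per assay and each C57BL/6 group 4. The labels number the replicates but do not say which came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

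The submitters' processing notes name HISAT2, featureCounts from Subread, Picard and DESeq2, tools usual for RNA-seq, and Bowtie2, SAMtools, MACS2, bedtools, DiffBind and HOMER, tools usual for ATAC-seq, with the genome build mm10. Their versions, their parameters, any read shift for the transposase, and the strand setting of the counting are not given in the sources used here. The authors deposited 2 RNA tables of normalized signal per gene and library. Low values in each column were whole multiples of 1 step, so each column was a read count divided by 1 factor, and 100% of values came out whole within a tolerance of 0.05 reads. The authors also deposited, per the file headers, a log2 fold change and an adjusted p-value for each pair of groups in both RNA tables. The 6 deposited ATAC lists held, per the file headers, the position of each region, log2 read concentrations per group, their difference as a log2 fold, a p-value and an FDR. Each ATAC value is the authors' own and is used here to describe, rank and filter regions within a list. From their values, 5 of the lists were restricted to an FDR of at most 0.05 and an absolute log2 fold of at least 1, whereas the list for 32 kPa against sham was restricted by FDR alone. Whether peaks were called per sample or on pooled samples is not given in the sources used here, and ATAC depth per library was not analysed here.

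The CD1 file held 27178 genes and the C57BL/6 file held 35972, and 24056 were named in both. Of the CD1 entries, 855 had no symbol and were left out of tests. They held 2.13 to 4.77% of the recovered reads of a library. Symbols turned into dates were found in 26 entries of the CD1 table and 25 of the C57BL/6 table, and were restored through the NCBI gene number where the table gave one. Recovered reads per library numbered 35858180 to 69524944 in CD1 and 14288605 to 51288435 in C57BL/6. Intervals and floors given for low counts cover counting error only. A gene with 0 reads in a group was set to a floor of 3 reads over the group, and a gene with 1 to 3 reads is given as a ratio with its 95% counting interval.

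The design fixed before the data were examined called for edgeR on raw counts or, for normalized values, for limma on log2(value + 1). The tables held normalized values, so limma was the main test. The comparisons, the gene lists, the rule for named genes and most alternative settings were also chosen before the data were examined. The deposited day 56 columns lay lower than the other C57BL/6 columns for the typical gene, so every table was first rescaled with 1 median-of-ratios factor per library over all its libraries, a choice made after seeing the data. Genes with a mean rescaled value of at least 1 were tested, 19102 in CD1 and 21134 in C57BL/6. Limma-trend was fitted to log2(rescaled value + 1), in 1 common fit per table with a group term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Tables were normalized separately, so tests between groups were made within a table. For the difference between the culture and the injury change, edgeR's quasi-likelihood test was run on the recovered reads of both tables. Levels are given as CPM, the recovered reads of a gene scaled by the total of its library, or as rescaled values, each with the SD between libraries.

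The 29 gene lists were fibrillar collagens and collagen processing, glycoproteins and elastic fibres, contractile genes, YAP and TAZ targets, TGF-beta responsive genes, an injury-induced fibroblast signature, cell cycle, markers of alveolar, adventitial and peribronchial fibroblasts, pericytes, smooth muscle, mesothelium, endothelium, epithelium, leukocytes and red cells, inflammatory fibroblast genes, interferon response, immediate-early and dissociation genes, matrix proteases and inhibitors, integrins and focal adhesion, glycolysis, cholesterol synthesis, lipid storage and PPARG targets, lung mesenchyme and activation transcription factors, senescence and p53 targets, and BMP and WNT signalling. Each list was tested with camera in limma with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. Named genes were, per comparison, the 6 highest and the 6 lowest called genes with groups that did not overlap and a CPM of at least 5 in the higher group, leaving out predicted genes and clones; a panel of 12 genes; and up to 4 called members of each list by size of change. For ATAC the rule took the 3 highest and 3 lowest folds of a list and the regions nearest to panel genes. A gene named outside this rule is said to be chosen after its values were seen.

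Regions were compared with bedtools with a smallest overlap of 1 bp. The 21 chromosome names of the lists matched those of the reference GRCm38 and 0 regions ended beyond a chromosome. Coordinates are 1-based on mm10. A region was given the gene and annotation in the authors' file or, in both lists against CD1 sham, which carry none, the nearest RefSeq transcription start site (TSS). Genes with only gained or only lost regions were compared with RNA calls by Fisher's exact test, two-sided. For motifs, 17 published consensus sequences were searched on both strands in 200 bp windows at the centre of regions farther than 1000 bp from a TSS, in 10 groups of GC content, and 7 regions with unknown bases were left out.

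Each test was first run on simulated data. With 200 of 21134 genes changed in a simulated day 14 comparison, limma recovered 24% of those changed by 1 log2 unit and 71% of those changed by 2, and called 6 unchanged genes. In the simulated comparison of 32 kPa with 0.2 kPa the shares were 58% and 83% of changed genes among 19102, with 8 unchanged genes called. For day 56 against sham they were 21% and 64%, with 6. DESeq2 called 56 unchanged genes in that simulated comparison. Alternative settings fixed in advance included DESeq2 on recovered reads, other edgeR normalizations and filters, other pseudocounts, stricter thresholds, a fit of only the groups compared, a replicate block and leaving out each library. Settings added after seeing the data were edgeR with TMM, the values as deposited, TMM scaling in limma, a higher filter, library weights, leaving out genes or regions of X and Y, leaving out the 4 C57BL/6 RNA libraries with the fewest genes detected or giving them a term, a term for Xist or Y genes, only libraries with Xist, DESeq2 calls for the return of the day 14 change, an absolute ATAC fold of at least 1, other annotation of regions, and list tests with some of these settings, with a replicate block or without 32 kPa replicate 3.

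Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1.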

Results

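The data described sorted lung mesenchymal cells of mice, the cells that make the collagen-rich matrix of the lung. RNA was measured in 21 libraries and accessible chromatin in 21. In CD1 mice, 3 libraries per assay came from freshly sorted sham cells, 3 from cells cultured on soft gels of 0.2 kPa and 3 from cells on stiff gels of 32 kPa. In C57BL/6 mice, 4 libraries per assay came from sham animals, 4 from day 14 and 4 from day 56 after bleomycin. The shallowest RNA libraries were at day 56.

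The most abundant transcript was Gsn, encoding the actin-severing protein gelsolin, in every sham library (4.46 to 9.19% of reads) and every day 56 library (5.80 to 6.90%). At day 14 it was Col3a1, encoding a fibrillar collagen (4.34 to 5.39%). Genes detected numbered 19171 to 19417 in CD1 sham, 17907 to 18149 on 0.2 kPa, and 16925, 16851 and 18456 in 32 kPa replicates 1, 2 and 3. C57BL/6 sham replicates 1 and 2 (16913 and 17561) and day 56 replicates 2 and 3 (16679 and 16563) had fewer genes detected than the other C57BL/6 libraries (19384 to 21381). Xist, transcribed from the inactive X of female cells, was present in all 9 CD1 libraries, in 1 of 4 sham, 2 of 4 day 14 and 4 of 4 day 56 C57BL/6 libraries. The remaining C57BL/6 libraries expressed the Y gene Ddx3y (112 to 134 CPM).

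The first comparison asked how 5 days on a soft gel changed lung mesenchymal cells relative to freshly sorted ones. Proliferation genes rose together: all 30 measured members of the cell cycle list were higher on 0.2 kPa than in sham, with a median log2 fold change of 4.95. Mki67, the proliferation marker, went from 4.19 to 164 CPM (5.18 ± 0.28, log2 fold change ± SE, n = 3 per group), Cdk1, the mitotic kinase, rose by 7.39 ± 0.20 and Ccnb1, its cyclin, by 7.33. Collagen transcripts fell: Col3a1 from 20908 to 283 CPM (-6.39 ± 0.16), Col1a1 to 0.212 of its sham value (-2.24 ± 0.21) and Col1a2 by a log2 fold change of -2.27 ± 0.17. Inmt, a methyltransferase abundant in lung fibroblasts, fell from 1727 to 0.0439 CPM (-14.92 ± 1.13).

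The genes that rose most were Prl2c2 (11.97 ± 0.25) and Prl2c3 (11.93 ± 0.19), prolactin-family genes so alike that reads can be shared between them, Hmga2, a fetal chromatin protein (9.91 ± 0.15), and Gsta2, a glutathione transferase (10.26 ± 0.15). The related Gsta1 had 0 reads in sham and was at least 3545-fold higher, with the same uncertainty about shared reads. Cck, a peptide hormone, had 2 reads in sham, a ratio of 3984 (95% counting interval 1102 to 32906). On the log2(value + 1) scale the genes that fell most besides Inmt were Clec3b, encoding tetranectin (-14.41 ± 0.81), Scara5, a ferritin receptor (-13.28 ± 1.10), the complement genes C7 (-13.21 ± 1.01) and C3 (-12.70 ± 0.61), and the transporter Slco2b1, which had 0 reads on 0.2 kPa and was at least 4698-fold lower.

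Markers of the resident fibroblast states fell. Among adventitial fibroblast markers 19 of 20 were lower and 1 higher (median -7.64), including Pi16 (-10.91 ± 0.38) and Dpp4 (-9.88). Alveolar fibroblast and lipofibroblast markers were lower for 19 of 23 members and higher for 2 (median -3.63), with Scn7a at -9.27 and the transcription factor Tcf21 at -2.71 ± 0.17. All 9 called peribronchial markers of 10 were lower (median -4.49), led by the Hedgehog target Gli1 (-8.19). Of 13 pericyte markers 11 were lower and 1 higher (median -4.40), with the channel genes Kcnj8 at -8.32 and Abcc9 at -8.14. Camera in limma gave adjusted p = 1.21e-08 for the adventitial, 1.95e-05 for the alveolar and 6.19e-04 for both the peribronchial and the pericyte list. Adjusted p = 0.0742 with an estimated correlation for the first 3 of these lists and 0.187 for pericytes. The cell cycle list had an adjusted p of 3.31e-18, and adjusted p = 0.0742 with an estimated correlation.

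Matrix genes fell on balance, with exceptions. Of 24 fibrillar collagen and processing genes 16 were lower and 7 higher (17 lower and 7 higher adjusted over the list alone), with Col6a2 at -6.72 and Col6a1 at -6.49. Glycoproteins and elastic fibre genes were lower for 18 and higher for 4 of 24, including the elastic fibre gene Mfap4 (-8.08) and the proteoglycan gene Dcn (-7.26). Postn, encoding periostin, fell by a log2 fold change of -1.54 ± 0.21, whereas Tnc, encoding tenascin C, rose by 3.13 ± 0.20 and Cthrc1, a gene of activated fibroblasts, by 2.34 ± 0.12. The camera adjusted p was 0.00305 for collagens (median -1.86) and 4.11e-04 for glycoproteins (median -1.89), and adjusted p = 0.193 and 0.117 with an estimated correlation. Matrix proteases and inhibitors were lower for 15 and higher for 4 of 22 (camera adjusted p 0.00532, median -2.38), and adjusted p = 0.0885 with an estimated correlation. The collagenase gene Mmp13 rose by 8.07 and Mmp2, a gelatinase, fell by 5.64.

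Lists tied to activation went both ways. YAP and TAZ targets were higher for 11 and lower for 6 of 22 (camera adjusted p 0.111), with Ankrd1 at 5.81 ± 0.24, Ctgf (Ccn2) at 1.17 ± 0.13 and Nt5e at -5.70. TGF-beta responsive genes were higher for 10 and lower for 6 of 19 (0.286), with the cytokine Il11 at 7.04 and Tgfbi at -8.90. The injury-induced fibroblast signature was higher for 11 and lower for 7 of 20 (0.133), with the BMP antagonist Grem1 at 9.75 ± 0.70 and Aspn at -7.67. Contractile genes were higher for 8 and lower for 7 of 18, with a median of 0.06 and a mean of -0.48 (0.538). Acta2, encoding smooth muscle actin, rose by 1.37 ± 0.49, a call lost without replicate 1, 2 or 3 of 0.2 kPa (1.38, 1.39 and 1.35). Without sham replicate 2, the lowest sham library for Acta2, the rise was 0.61. Integrin and focal adhesion genes were higher for 8 and lower for 12 of 22 (0.613).

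Activation transcription factors were higher for 14 and lower for 5 of 24 (camera adjusted p 0.00532), and adjusted p = 0.0742 with an estimated correlation. Among them Fosl1, an AP-1 subunit, rose by 6.81, Tead4 by 4.96 and Runx1 by 2.13 ± 0.14. Lung mesenchyme transcription factors were lower for 14 and higher for 4 of 24 (0.00744), and adjusted p = 0.203 with an estimated correlation, with Meox2 at -4.75 and Tbx4 at -3.25. Every one of 20 immediate-early and dissociation genes was lower (median -3.84), with Fos at -9.53 ± 0.18 and Egr1 at -5.74. Every one of 20 interferon response genes was lower as well (median -2.87), with Oasl2 at -5.12. Their camera adjusted p values were 9.06e-09 and 6.66e-06, and adjusted p = 0.117 and 0.0742 with an estimated correlation. Inflammatory fibroblast genes were lower for 16 and higher for 6 of 22 (0.00566), and adjusted p = 0.0742 with an estimated correlation; the chemokine Ccl11 fell by 8.65 and Il1rl1, the IL-33 receptor, rose by 8.10. BMP and WNT genes were lower for 15 (16 adjusted over the list alone) and higher for 4 of 22 (0.0111), and adjusted p = 0.0925 with an estimated correlation, with the WNT inhibitor Wif1 at -6.66.

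Metabolic genes rose in part. Cholesterol synthesis genes were higher for 16 and lower for 1 of 20 (median 1.49, camera adjusted p 5.52e-05), and adjusted p = 0.187 with an estimated correlation. Glycolysis genes were higher for 11 and lower for 5 of 20 (median 1.52, 0.00532), and adjusted p = 0.169 with an estimated correlation, with enolase Eno1 at 3.93 and Pkm at 3.20. Senescence and p53 targets were higher for 11 and lower for 3 of 16 (0.0139), and adjusted p = 0.163 with an estimated correlation, with the cell cycle inhibitor Cdkn2a at 5.27. Lipid storage and PPARG targets were higher for 7 and lower for 11 of 18 (0.548). Pparg itself, the adipogenic receptor, rose by 1.33 ± 0.21 and the fatty acid carrier Cd36 fell by 5.22.

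Markers of other cell types fell in culture together with the fibroblast groups. Epithelial markers were lower for 18 of 18 (median -5.90, or -5.97 with zero-read genes at their bound), and Sftpc, the surfactant gene of alveolar epithelium, had 2 reads, a ratio of 7161 lower (95% counting interval 1982 to 59134). Endothelial markers were lower for 15 and higher for 1 of 18 (median -4.05), 16 and 1 adjusted over the list alone. Leukocyte markers were lower for 19 and higher for 1 of 22 (median -4.12, or -4.07 at the bound), with Cd74 at -9.88. Red cell genes were lower for 4 of 5 (median -5.33, or -5.52 at the bound), smooth muscle markers lower for 9 and higher for 1 of 12 (median -2.77), and mesothelial markers lower for 10 and higher for 1 of 12 (median -3.72). The camera adjusted p values were 9.89e-06 (epithelial), 4.11e-04 (endothelial), 4.53e-04 (leukocyte), 0.0461 (red cell), 0.0314 (smooth muscle) and 0.0316 (mesothelial). In the same order, adjusted p = 0.143, 0.0925, 0.217, 0.256, 0.463 and 0.463 with an estimated correlation, and for red cell genes 0.0526 on the values as deposited.

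Over all 19102 genes tested, limma called 6038 higher and 7452 lower on 0.2 kPa than in sham, 4058 and 5810 of them by at least 1 log2 unit. The groups did not overlap for 76.1% of genes, where chance gives 10%. The median change of all genes was -0.22, and 0.08 when edgeR scaled by total reads alone. No list call held with an estimated correlation.

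The same question was asked of the stiff gel. On 32 kPa, Mki67 reached 141 CPM (5.01 ± 0.28 over sham, n = 3 per group), and all 30 cell cycle genes were again higher (median 5.04). Col3a1 fell to 223 CPM (-6.67 ± 0.16), Col1a1 by a log2 fold change of -2.18 ± 0.21, Col1a2 by -2.33 and Postn by -1.61. Tnc rose by 3.08, Cthrc1 by 1.52 ± 0.12, Ankrd1 by 5.87, Ctgf to 2.30 times its sham value, Acta2 by 1.65 ± 0.49 (0.90 without sham replicate 2) and Runx1 by 2.35 ± 0.14. Tcf21 fell by a log2 fold change of -2.86 ± 0.17. Pparg was 0.63 ± 0.21 higher, a call lost without 32 kPa replicate 1 (0.60), 32 kPa replicate 3 (0.50) or sham replicate 1 (0.50).

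The genes with the largest changes were largely those of the soft gel: Hmga2 (9.91 ± 0.15), Prl2c2 (11.48), Prl2c3 (11.29) and Gsta2 (10.12) rose, and Gsta1, with 0 reads in sham, was at least 3097-fold higher. Inmt (-14.12 ± 1.13; -12.94 without 32 kPa replicate 2 and -15.84 without replicate 3), C7 (-13.57), Scara5 (-13.49), Clec3b (-12.42), Galnt15, a glycosyltransferase (-12.06 ± 0.84), and C3 (-11.98) fell. Adventitial markers were lower for 19 of 20 (median -7.77), alveolar markers lower for 19 and higher for 2 of 23 (median -3.85), peribronchial markers lower for 9 of 10 (median -4.65) and pericyte markers lower for 11 and higher for 1 of 13 (median -4.73, or -4.65 at the bound). The camera adjusted p was 1.88e-17 for cell cycle, 2.94e-08 for adventitial, 1.84e-05 for alveolar and 7.12e-04 for peribronchial and pericyte genes. Adjusted p = 0.0743 with an estimated correlation for each of these but pericytes (0.178).

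Collagen genes were lower for 16 and higher for 4 of 24 (17 and 6 adjusted over the list alone; median -1.64, camera adjusted p 0.00199), and adjusted p = 0.188 with an estimated correlation. Glycoproteins were lower for 18 and higher for 4 of 24 (3.31e-04), and adjusted p = 0.122 with an estimated correlation. Immediate-early genes were lower for 19 of 20 (8.45e-08), with Fos at -9.60 ± 0.18, and interferon genes lower for 20 of 20 (5.65e-06), and adjusted p = 0.140 and 0.0743 with an estimated correlation. Glycolysis genes were higher for 12 and lower for 5 of 20 (0.00199), and cholesterol genes higher for 15 and lower for 2 of 20 (2.01e-04), and adjusted p = 0.145 and 0.203 with an estimated correlation. Activation transcription factors were higher for 14 and lower for 6 of 24 (0.00571), and adjusted p = 0.0782 with an estimated correlation. YAP and TAZ targets were higher for 12 and lower for 6 of 22 (0.0882), TGF-beta genes higher for 10 and lower for 8 of 19 (0.341, median 0.51 and mean -0.16), the injury signature higher for 10 and lower for 8 of 20 (0.242), and contractile genes higher for 8 and lower for 7 of 18 (0.474, median 0.07 and mean -0.45).

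Of the markers of other cell types, epithelial genes were lower for 18 of 18, leukocyte genes for 20 of 22, endothelial genes for 16 of 18 with 1 higher, mesothelial genes for 10 of 12 with 1 higher, smooth muscle genes for 9 of 12 with 1 higher and red cell genes for 4 of 5. The camera adjusted p values were 1.84e-05, 2.01e-04, 7.13e-04, 0.0219, 0.0455 and 0.0799, the smooth muscle value being 0.0506 on the values as deposited. Adjusted p = 0.148, 0.203, 0.113, 0.459 and 0.499 with an estimated correlation for the first 5. Inflammatory genes (16 lower, 6 higher, 0.00714), proteases (16 lower, 4 higher, 0.00521) and BMP and WNT genes (16 lower, 4 higher, 0.00714) each had adjusted p = 0.0782 with an estimated correlation. Lung mesenchyme factors (15 lower, 5 higher, 0.0165) and senescence genes (10 higher, 3 lower, 0.0155) had adjusted p = 0.248 and 0.156 with an estimated correlation. Integrin (9 higher, 12 lower, 0.747) and lipid genes (5 higher, 10 lower, 0.482) did not pass.

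Limma called 6152 genes higher and 7805 lower on 32 kPa than in sham, 4292 and 6202 by at least 1 log2 unit, and the groups did not overlap for 72.9% of genes against 10% by chance. The soft and stiff changes shared their sham libraries: their correlation across genes was 0.978, where simulated unchanged groups gave 0.501, and their covariance was 5.46 against 0.0845. Both called 5694 genes higher (1945 for independent lists) and 7043 lower (3045), with 0 called in opposite directions by limma. With 3 sham libraries the controls could not be split into parts of 2, so part of the excess may come from the shared shams.

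The direct comparison of 32 kPa with 0.2 kPa asked whether stiffness itself changed expression. Of canonical stiffness readouts, Ctgf differed by 0.03 ± 0.13, Ankrd1 by 0.06 ± 0.24 and Col1a1 by 0.06 ± 0.21 (log2 ± SE, n = 3 per group), each smaller than its error. Acta2 differed by 0.28 ± 0.49, an error that pools the wider sham spread. Its rescaled reads were 147797, 142268 and 111725 against 106714 to 112898. The lowest adjusted p values in limma belonged to Adamtsl2, a microfibril-associated gene (9.09 ± 4.17 against 63.9 ± 7.14 rescaled reads, mean ± SD; adjusted p = 0.0633), Serpina3n, a protease inhibitor (420 ± 16.2 against 724 ± 26.2; 0.0641), and Spp1, encoding osteopontin (24.3 against 83.6 CPM; 0.0805). These 3 genes, chosen after their values were seen, were lower on the stiff gel. Cthrc1 was -0.82 ± 0.12 (adjusted p = 0.113) and Pparg -0.71 ± 0.21 (0.759). The other panel values were Col1a2 -0.06, Postn -0.07, Tnc -0.04, Mki67 -0.17, Tcf21 -0.15 and Runx1 0.22, none past the threshold.

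Small shifts of whole lists passed camera in limma with its preset correlation. The injury-induced fibroblast signature was lower on 32 kPa (median -0.18, 6 lower adjusted over the list alone, adjusted p 1.01e-04), as were glycoproteins (0.00441, median -0.21), BMP and WNT genes (0.00441, 3 lower alone), proteases (0.00612), collagens (0.0122, median -0.09), leukocyte (0.0271), cholesterol (0.0272) and interferon genes (0.0339). Immediate-early genes (0.00263, median 0.26, 4 higher alone) and glycolysis genes (0.0134) were higher. In this order, adjusted p = 0.179, 0.492, 0.179, 0.179, 0.518, 0.584, 0.584, 0.515, 0.518 and 0.515 with an estimated correlation, so none held. Without 32 kPa replicate 3, at the preset correlation, the leukocyte (0.250), cholesterol (0.267), interferon (0.127), BMP and WNT (0.0839) and glycolysis calls (0.0814) were lost. The calls of the injury signature (4.97e-04), glycoproteins (0.00193), immediate-early genes (0.00178), proteases (0.0486) and collagens (0.0486) held. With an estimated correlation none did (0.144 for the injury signature).

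Limma called 0 genes higher and 0 lower, with 1020 genes (5.34%) at an unadjusted p under 0.05. On recovered reads edgeR called 0 higher and 1 lower and DESeq2 2 and 37, whereas limma with library weights, a setting chosen after seeing the data, called 2399 and 2261. Groups did not overlap for 9.03% of genes, where chance gives 10%. The authors' deposited table held, at an FDR under 0.05, 4 genes higher on 32 kPa and 38 lower, among them Spp1 (log2 -1.70, FDR 2.2e-09), Cthrc1 (-0.81, 4.8e-05), Adamtsl2 (-2.75, 2.64e-05), the cytokine Il11 (-0.75) and the matrix gene Mgp (-1.12).

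Replicate 3 of 32 kPa lay with the soft libraries on the first 2 principal components of the CD1 table, which held 83.9% and 4.57% of the variance, at -98.3 and 36.7, near 0.2 kPa replicate 1 at -101 and 36.2. Replicates 1 and 2 of 32 kPa lay at -131 and -37.0 and at -132 and -72.2. In replicates 1 and 2 Rn45s, the ribosomal precursor transcript, was the top gene with 1.499% and 1.86% of reads, entries without a symbol held 4.31% and 4.77% and 16925 and 16851 genes were detected. Replicate 3 had Eef1a1 on top (1.03%), 3.03% in such entries and 18456 genes. Without 32 kPa replicate 3, limma called 479 genes higher and 623 lower, against 0 and 1 without replicate 1 and 0 and 2 without replicate 2. Genes called without it included Gapdh (2.24, a gene with many pseudogenes and so uncertain), Dpm3 (1.48), Jund (1.44) and the cytokine suppressor Socs1 (1.37) on the higher side, and Fam171b (-2.42), Igfbp5 (-2.15), Peg3 (-2.08) and Pcdhgc3 (-1.89) on the lower. Cthrc1 was then -0.72 (adjusted p = 0.0124), and Col1a1 (0.13), Acta2 (0.41), Ctgf (0.03) and Ankrd1 (-0.02) stayed outside the threshold.

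The injury comparison asked what bleomycin did to Col1a2-lineage mesenchyme after 14 days. Fibrillar collagens rose: Col1a1 from 2833 to 15936 CPM (2.54 ± 0.24, log2 fold change ± SE, n = 4 per group), Col1a2 by 1.66 ± 0.22 and Col3a1, named after its values were seen, from 12971 to 48413 CPM. Cthrc1 went from 2.79 to 332 CPM (7.16 ± 0.40) and Spp1 from 26.5 ± 12.5 to 10489.5 ± 3477 CPM (mean ± SD; 8.74 ± 0.31, limma adjusted p = 1.67e-09). Mki67 rose from 0.381 to 34.0 CPM (7.24 ± 0.94; 6.21 without sham replicate 1 and 7.87 without replicate 3). Inmt fell from 6046 to 427 CPM (-3.73 ± 0.26) and Tcf21 from 224 to 72.8 CPM (-1.59 ± 0.21).

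The largest rises were of the adhesion gene Chl1 (10.14, adjusted p = 7.48e-05), Grem1 (9.63 ± 1.32), the protease inhibitor Serpinb2 (9.18 ± 0.79), Spp1, the cytokine Tnfsf18 (8.62 ± 1.10) and the collagenase Mmp13 (8.58 ± 1.04). The largest falls among genes that kept their call without any single library were of Angptl1 (-4.64 ± 0.86), the collagen glycosyltransferase Colgalt2 (-4.53 ± 0.50), the amino acid transporter Slc7a10 (-4.21 ± 0.47), Colq (-4.20 ± 0.34) and Sec14l4 (-4.13 ± 0.77). Tnc rose by 5.74 ± 0.56, Postn by 1.99 ± 0.35, Runx1 by 2.24 ± 0.38, Ankrd1 by 2.91 ± 0.66 (2.26 without sham replicate 1), Ctgf by 1.26 ± 0.17 and Acta2 by 0.71 ± 0.15. Pparg was -0.73 ± 0.36 (adjusted p = 0.198).

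**Figure D1:**
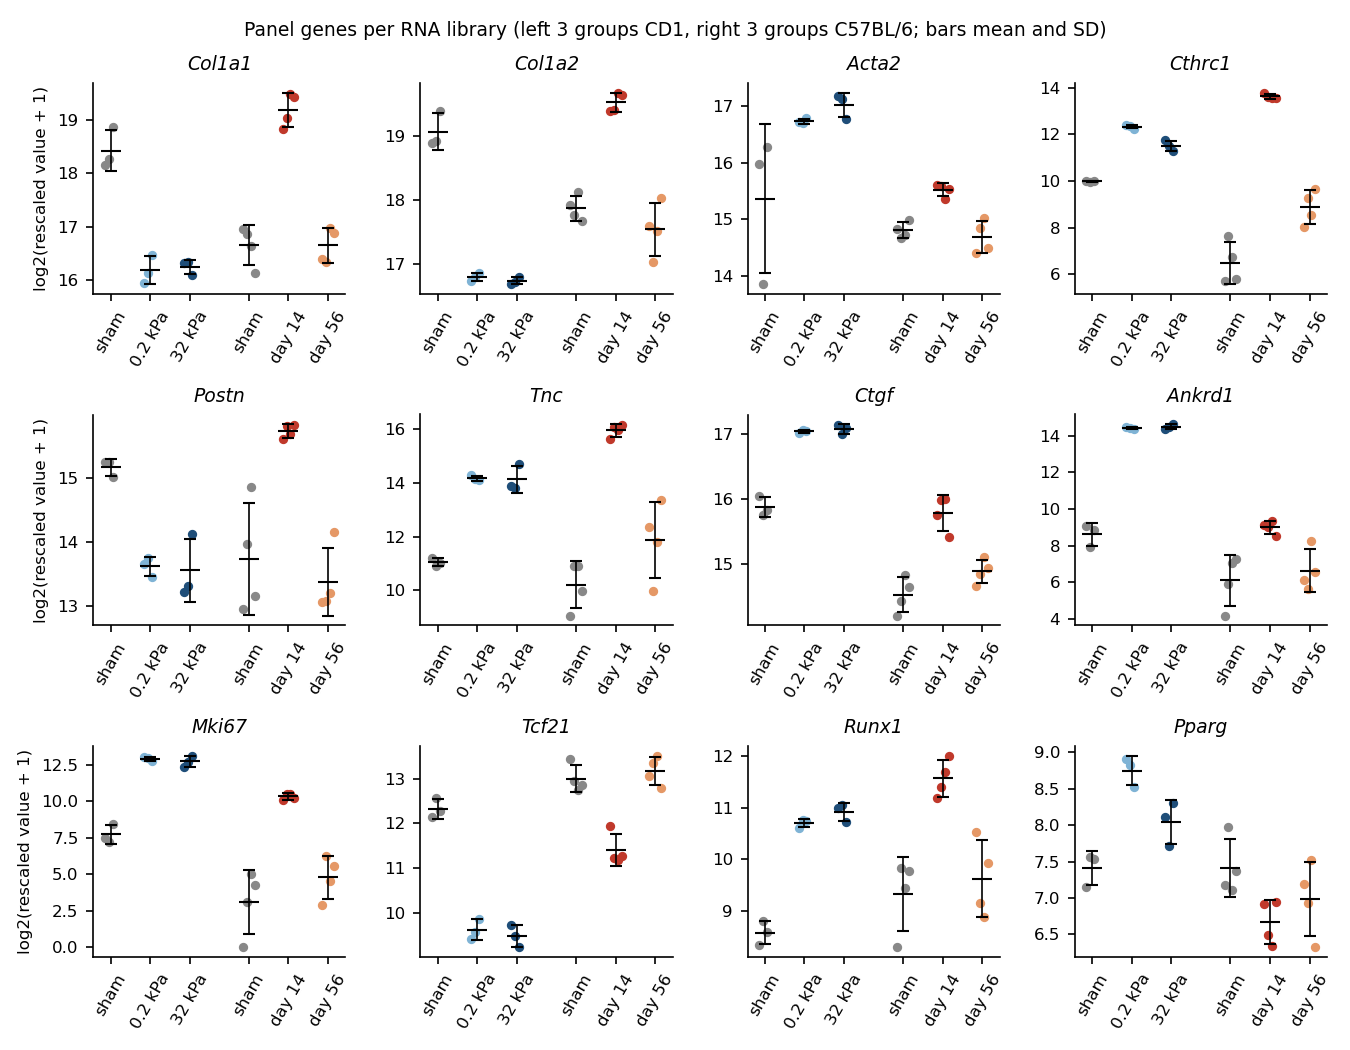
Levels of the 12 panel genes in each RNA library, as log2(rescaled value + 1), with CD1 sham, 0.2 kPa and 32 kPa on the left of each panel and C57BL/6 sham, day 14 and day 56 on the right. Points are libraries and bars give the mean and SD of 3 or 4 libraries. Strains were scaled separately. Col1a1 lies below sham in culture (-2.24 and -2.18) and above sham at day 14 (2.54).

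Matrix lists rose at day 14. Of 24 collagen and processing genes 18 were higher and 0 lower (19 and 0 adjusted over the list alone; median 1.34), with Col11a1 at 6.67 ± 1.46 and the prolyl hydroxylase P4ha3 at 3.10. Glycoproteins were higher for 13 and lower for 6 of 24 (15 and 6 alone), with fibronectin Fn1 at 3.52 ± 0.40 and elastin Eln at 2.74 ± 0.26. The injury-induced fibroblast signature was higher for 16 of 20 (median 2.44), and TGF-beta genes were higher for 10 and lower for 2 of 19 (13 and 2 alone), with Adam12 at 6.62, Lrrc15 at 4.98 and the activin subunit Inhba at 3.13 ± 0.18. Camera in limma gave adjusted p = 2.53e-13 for collagens, 0.00234 for glycoproteins, 6.39e-15 for the injury signature and 6.96e-05 for TGF-beta genes. Adjusted p = 0.0644, 0.244, 0.0215 and 0.0133 with an estimated correlation, so the calls of the last 2 held.

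Cell cycle genes were higher for 24 of 30 (26 alone; median 3.48), with the mitotic kinase Plk1 at 7.99, Top2a at 7.71 and Bub1 at 7.05. The list's camera adjusted p was 2.69e-19, and adjusted p = 0.0133 with an estimated correlation. Lung mesenchyme transcription factors were lower for 11 of 24 and higher for 0 (12 and 1 alone; median -0.60, camera adjusted p 4.07e-06), and adjusted p = 0.0133 with an estimated correlation, with Twist2 at -1.13. Alveolar markers were lower for 15 and higher for 1 of 23 (17 and 1 alone; median -1.13, 3.97e-11), and adjusted p = 0.0644 with an estimated correlation, with the growth factor receptor Fgfr4 at -2.45. Adventitial markers were lower for 11 and higher for 2 of 20 (6.96e-05), with Dpp4 at -3.72 and Adh7 at -2.79. Peribronchial markers were lower for 5 of 10 (5.82e-04), with Enpp2 at -1.76. Pericyte markers were lower for 4 and higher for 1 of 13 (6 and 1 alone; 0.00547), with Higd1b at -2.35 and the proteoglycan gene Cspg4 at 2.63. For these 3 lists adjusted p = 0.244, 0.068 and 0.269 with an estimated correlation.

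Inflammatory fibroblast genes were higher for 11 and lower for 1 of 22 (12 and 2 alone; camera adjusted p 5.91e-04), led by the acute-phase gene Saa3 (6.02 ± 0.38), Il1rl1 (5.89) and the lipocalin Lcn2 (5.19 ± 0.40), and adjusted p = 0.269 with an estimated correlation. Proteases were higher for 11 and lower for 3 of 22 (12 and 4 alone; 1.14e-04), with Mmp12 at 6.28 and Mmp10 at 5.27, and adjusted p = 0.068 with an estimated correlation. Immediate-early genes were lower for 12 of 20 (14 alone; median -1.24, 1.04e-12), with Nr4a1 at -2.05 and Egr1 at -1.82, and adjusted p = 0.068 with an estimated correlation. Glycolysis genes were higher for 8 and lower for 3 of 20 (9 and 3 alone; 0.01002), with the hexokinase Hk2 at 2.67, and adjusted p = 0.171 with an estimated correlation. Contractile genes were higher for 7 and lower for 2 of 18 (8 and 3 alone; 0.0413), with Actg2 at 1.72 and Lmod1 at -1.37, and adjusted p = 0.474 with an estimated correlation and 0.0625 with a term for Xist or Y genes.

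Markers of other cell types moved apart at day 14. Leukocyte markers were higher for 15 of 22 (16 alone; median 2.24, camera adjusted p 5.7e-09), and adjusted p = 0.128 with an estimated correlation, including the macrophage genes Chil3 (3.68 ± 0.73) and Adgre1 (3.06) and the neutrophil gene S100a8 (3.47). Epithelial markers were lower for 4 of 18 (5 lower and 1 higher alone; median -1.05, 0.0168), and adjusted p = 0.244 with an estimated correlation, with Sftpc at -3.12 ± 0.41 and Sftpa1 at -3.29. Endothelial markers were higher for 1 and lower for 4 of 18, with a median of 0.27 while camera pointed down (0.73). Red cell genes had 0 of 6 called in limma (median 1.04, 0.235), with 0 adjusted over the list alone. Mesothelial genes were higher for 1 and lower for 1 of 12 (0.588) and smooth muscle genes higher for 3 and lower for 4 of 12 (0.492).

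The remaining lists did not pass camera at day 14. YAP and TAZ targets were higher for 4 and lower for 5 of 22 (median -0.22, mean 0.08, adjusted p 0.252), with Igfbp3 at -2.28 and Cyr61 at -1.68. Interferon genes were higher for 4 and lower for 3 of 20, with a median of 0.04 while camera pointed down (0.845). Integrin genes were higher for 4 and lower for 4 of 22 (0.263), with Itga5 at 2.69 and Itga8 at -1.70. Cholesterol genes were higher for 4 and lower for 2 of 20 (0.188), lipid genes higher for 4 and lower for 2 of 18 (0.573), with Fabp4 at 2.56, activation factors higher for 5 of 24 (0.0822), with Etv4 at 6.30 and Runx2 at 4.17, senescence genes higher for 5 and lower for 2 of 16 (0.105), with Cdkn2b at 2.30, and BMP and WNT genes higher for 4 and lower for 4 of 22 (median -0.37, mean 0.37, 0.365), with Lef1 at 2.56.

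At day 14 limma called 2016 genes higher and 1343 lower than sham of 21134, 1327 and 819 by at least 1 log2 unit. The share higher was 60.02%, against 52.4% with edgeR and TMM scaling, 50.2% scaled by total reads and 48.5% among genes of at least 1 CPM. Without day 14 replicate 2 the count higher was 1339. With a term for Xist or Y genes 1647 and 1112 genes were called and without the 4 libraries with the fewest genes detected 3036 and 2247. With library weights limma called 3890.0 and 3502.

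Day 56 against sham asked what remained at the later time. Col1a1 was back at 2972 CPM against 2833 in sham (0.00 ± 0.24, n = 4 per group), Mki67 at 1.06 CPM and Tcf21 at 270 CPM (0.18). Only 1 gene passed limma: Angpt4, an angiopoietin ligand of the Tie2 receptor, was lower, at 27.9 ± 0.87 against 77.7 ± 13.6 CPM (-1.54 ± 0.19, adjusted p = 0.0186). That call was lost without sham replicate 1 (-1.58) or 4 (-1.45) or day 56 replicate 1 (-1.53), 2 (-1.55) or 3 (-1.54). Cthrc1 was at 14.6 CPM against 2.79 (2.40 ± 0.40, adjusted p = 0.0608) and Spp1 at 96.5 ± 19.0 against 26.5 ± 12.5 CPM (1.89 ± 0.31, 0.0546), after 332 and 10489.5 CPM at day 14. Serpine2, encoding a protease inhibitor, was at 1003 ± 83 against 437 ± 88 CPM (1.14 ± 0.17, 0.0546), and Nnat and Chodl differed by 2.60 and 2.28 at the same adjusted p; these genes were chosen after their values were seen.

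The other panel values were Col1a2 -0.33, Acta2 -0.12, Postn -0.36, Tnc 1.66 ± 0.56 (adjusted p = 0.696), Ctgf 0.36, Ankrd1 0.54, Runx1 0.29 and Pparg -0.42, none past the threshold. The authors' deposited table held, at an FDR under 0.05, 39 genes higher and 25 lower at day 56, with Angpt4 at -1.56 (1.77e-13), Chodl at 2.29 (2.66e-12) and Serpine2 at 1.13 (5.87e-07). With a term for the 4 libraries with the fewest genes detected, limma called 7 higher and 2 lower, the latter Angpt4 (0.0193) and the Tie2 receptor gene Tek (-1.28, 0.0397). Chl1, the gene with the largest rise at day 14, was among the 7 (5.56, 0.0429).

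Camera in limma placed adventitial (median -0.44, adjusted p 1.77e-06), epithelial (-1.39, 7.05e-07), red cell (-1.67, 3.27e-06), pericyte (0.0135) and contractile genes (0.0429) lower at day 56 than in sham. In this order, adjusted p = 0.268, 0.0771, 0.0771, 0.488 and 0.646 with an estimated correlation. The injury signature (median 0.32, 0.0016), cholesterol (5.38e-04), interferon (0.00541), senescence (0.00541), TGF-beta (0.019), leukocyte (0.24, 0.0219) and BMP and WNT genes (0.0369) were placed higher, and adjusted p = 0.38, 0.38, 0.476, 0.214, 0.146, 0.646 and 0.268 with an estimated correlation. Of these, TGF-beta, senescence and BMP and WNT genes also missed the threshold on the values as deposited (0.130, 0.0732 and 0.217) and with a term for Xist or Y genes, where the leukocyte list missed it too (0.193, 0.193, 0.481 and 0.488). Adjusted over the list alone, 5 epithelial genes and 5 of 6 red cell genes were lower and 2 injury signature and 2 TGF-beta genes higher. Collagens (-0.08, 0.923), cell cycle (0.02, 0.545) and alveolar genes (0.02, 0.71) did not differ past the threshold. Mesothelial (median 0.22, mean -0.19), inflammatory (-0.12, 0.09) and lung mesenchyme factors (-0.03, 0.05) had medians and means of different sign, and the protease list had a median of -0.02 where camera pointed up.

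Limma called 0 genes higher and 1 lower of 21134 tested, with 1330 genes (6.29%) at an unadjusted p under 0.05. On recovered reads edgeR called 0 and 1 and DESeq2 59 and 28. Without sham replicate 2 or 3 the count higher was 2, and without day 56 replicate 4 it was 1. All 4 day 56 RNA libraries had Xist against 1 of 4 in sham, and with a term for this 0 genes were called by limma.

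Day 56 against day 14 asked which injury changes receded. Col1a1 fell from 15936 to 2972 CPM (-2.54 ± 0.24, n = 4 per group), Cthrc1 from 332 to 14.6 CPM (-4.75 ± 0.40), Spp1 from 10489.5 to 96.5 CPM (-6.85 ± 0.31) and Mki67 from 34.0 to 1.06 CPM (-5.54 ± 0.94; -4.90 without day 56 replicate 1). Inmt rose from 427 to 4698 CPM (3.34 ± 0.26) and Tcf21 from 72.8 to 270 CPM (1.78 ± 0.21). The largest falls were of Serpinb2, with 2 reads at day 56 and a ratio of 1609 (95% counting interval 445 to 13287), Mmp13 (-8.29 ± 1.04), the kinesins Kif18b (-7.73 ± 0.88) and Kif4 (-7.68 ± 1.05), Klhdc8a (-7.60 ± 0.95) and the checkpoint kinase Bub1 (-7.46 ± 1.10). The largest rises were of Angptl1 (4.58 ± 0.86), Slc7a10 (3.86 ± 0.47), Thsd7b (3.80 ± 0.66), Colgalt2 (3.79 ± 0.50) and Colq (3.65 ± 0.34).

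Within the panel Col1a2 fell by a log2 fold change of -1.99, Postn by -2.35 ± 0.35, Tnc by -4.08 ± 0.56 (-3.45 without day 56 replicate 2), Runx1 by -1.95 ± 0.38, Ctgf by -0.90 ± 0.17 and Acta2 by -0.83 ± 0.15. Ankrd1 was -2.36 ± 0.66, a call lost without day 14 replicate 1, 2 or 3 (-2.33, -2.35 and -2.24) or day 56 replicate 1, 2 or 4 (-2.19, -2.02 and -2.34), and Pparg was 0.32 (adjusted p = 0.623). Collagens were lower for 17 of 24 (19 lower and 1 higher alone; median -1.43), with Lox, the collagen crosslinking enzyme, at -2.63, and glycoproteins lower for 13 and higher for 6 of 24 (16 and 6 alone), with Fn1 at -3.23. The injury signature was lower for 16 of 20 (16 lower and 1 higher alone; median -2.43), TGF-beta genes were lower for 9 and higher for 3 of 19 (10 and 3 alone), with Lrrc15 at -5.85, and cell cycle genes were lower for 24 of 30 (26 alone; median -3.45), with Plk1 at -7.33. Alveolar markers were higher for 14 of 23 (16 higher and 2 lower alone; median 1.05), with Fgfr4 at 2.54, and lung mesenchyme factors higher for 9 of 24 (12 alone; median 0.60), with Tbx2 at 1.18. The camera adjusted p in limma was 1.4e-13 for collagens, 0.0105 for glycoproteins, 6.41e-13 for the injury signature, 0.00227 for TGF-beta, 1.08e-19 for cell cycle, 6.3e-13 for alveolar and 4.39e-07 for lung mesenchyme genes. In this order, adjusted p = 0.0593, 0.3, 0.0413, 0.0413, 0.0115, 0.0413 and 0.0115 with an estimated correlation.

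Immediate-early genes were higher for 11 of 20 (14 alone; camera adjusted p 4.77e-12), with Nr4a1 at 1.83, and peribronchial markers higher for 3 of 10 (4 alone; 0.00227), with Enpp2 at 2.04, and adjusted p = 0.0742 and 0.0947 with an estimated correlation. Adventitial markers were higher for 8 and lower for 2 of 20 (0.0448), and adjusted p = 0.545 with an estimated correlation and 0.103 on the values as deposited. Leukocyte markers were lower for 12 of 22 (16 alone; median -1.69, 3.67e-07), with Csf1r at -2.46 ± 0.44, and red cell genes lower for 4 of 6 (4.52e-04), with the haemoglobin gene Hbb-bs at -2.97, and adjusted p = 0.154 and 0.0742 with an estimated correlation. Inflammatory genes were lower for 11 of 22 (12 lower and 1 higher alone; 1.87e-05), with Saa3 at -5.17, and proteases lower for 11 and higher for 1 of 22 (12 and 2 alone; 4.95e-05), with Mmp10 at -5.32, and adjusted p = 0.177 and 0.0614 with an estimated correlation. Glycolysis (9 lower, 1 higher, 0.00102), contractile (8 lower, 0.00151), activation factor (6 lower, 1 higher, 0.015) and integrin genes (5 lower, 3 higher, 0.0448) were placed lower, and adjusted p = 0.0742, 0.272, 0.154 and 0.503 with an estimated correlation.

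The lists that did not pass at day 56 against day 14 were YAP and TAZ targets (4 higher, 5 lower, 0.583), pericyte (4 higher, 1 lower, 0.124), smooth muscle (1 higher, 3 lower, median 0.33, mean -0.04, 0.894), mesothelial (1 lower, 0.657), endothelial (1 higher, 0.908), epithelial (1 higher, 0.883), interferon (2 higher, 0.0515), cholesterol (2 higher, 1 lower, 0.583), lipid (1 higher, 3 lower, 0.357), senescence (2 higher, 4 lower, 0.854) and BMP and WNT genes (5 higher, 4 lower, median 0.40, mean -0.10, 0.0515). Limma called 1204 genes higher and 1792 lower at day 56 than at day 14. The share higher was 40.2%, against 20.4% on the values as deposited (777 and 3035 genes), where the median change of all genes was -0.27 in place of -0.08, and 51.3% with edgeR and TMM and 61.1% scaled by total reads. Without day 14 replicate 2 the counts were 753 and 1109, without day 14 replicate 3 the count higher was 781, and with a term for Xist or Y genes they were 730 and 1193.

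The day 14 calls were traced to day 56. Of 2016 genes higher at day 14, 1396 (69.2%) were called lower at day 56 than at day 14 and 0 were still called higher than sham by limma. Of 1343 lower genes, 893 (66.5%) were called back up and 1, Angpt4, was still called. With DESeq2, 46 of 2336 higher and 14 of 2001 lower genes were still called. The median share of the day 14 change left at day 56 was 12.1% for higher and 14.5% for lower genes. For Cthrc1, 2.40 of 7.16 log2 units was left, a larger share. Simulations with day 56 equal to sham gave 78.6% and 73.1% called back, with 5.57% and 8.20% of the change left. They called about 2985 and 2137 genes at day 14, so they are no matched reference. With day 56 equal to day 14, 0% were called back. The 2 changes share the day 14 libraries: their correlation across genes was -0.797 against -0.501 for simulated unchanged groups, with covariances of -1.203 and -0.197, and over 6 splits of the day 14 libraries the means were -0.637 and -1.05. The 2289 genes called in opposite directions compared with 0 in simulated unchanged groups. Almost no gene is called there, so that 0 does not gauge the shared libraries' part. The day 14 and day 56 changes against the shared sham correlated at 0.364, against 0.231 simulated with day 56 unchanged, with covariances of 0.355 and 0.195, and over 6 splits of the shams at 0.0652 (covariance 0.0820).

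A further question was whether culture brought cells toward the injured state. The changes on 32 kPa and at day 14 came from different animals, strains and tables, with no shared libraries, and 16425 genes were tested in both. Proliferation was common to both: 24 of 30 cell cycle genes were higher in each, and Mki67 was 5.05 higher in culture and 6.57 higher at day 14 (edgeR log2 fold changes; difference -1.51, adjusted p = 0.111). Fibrillar collagens went apart: 10 of 24 collagen list genes were lower in culture and higher at day 14, against 4 higher in both, and Col1a1 was -2.12 in culture against 2.52 at day 14 (difference -4.64, adjusted p = 8.78e-10). Col3a1 (-6.58 against 1.92), Lcn2 (-4.62 against 5.25) and Fn1 (-0.87 against 3.44) also differed (adjusted p = 7.55e-13, 4.94e-08 and 8.99e-07 in edgeR), as did Saa3, which had 0 reads on 32 kPa, at least 65.9-fold lower than in sham, and was 5.83 higher at day 14 (adjusted p = 1.46e-09). Grem1 (8.71 and 8.80), Runx1 (2.44 and 2.15), Ctgf (1.30 and 1.24) and Acta2 (1.43 and 0.69) were not past the threshold for a difference.

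**Figure D2:**
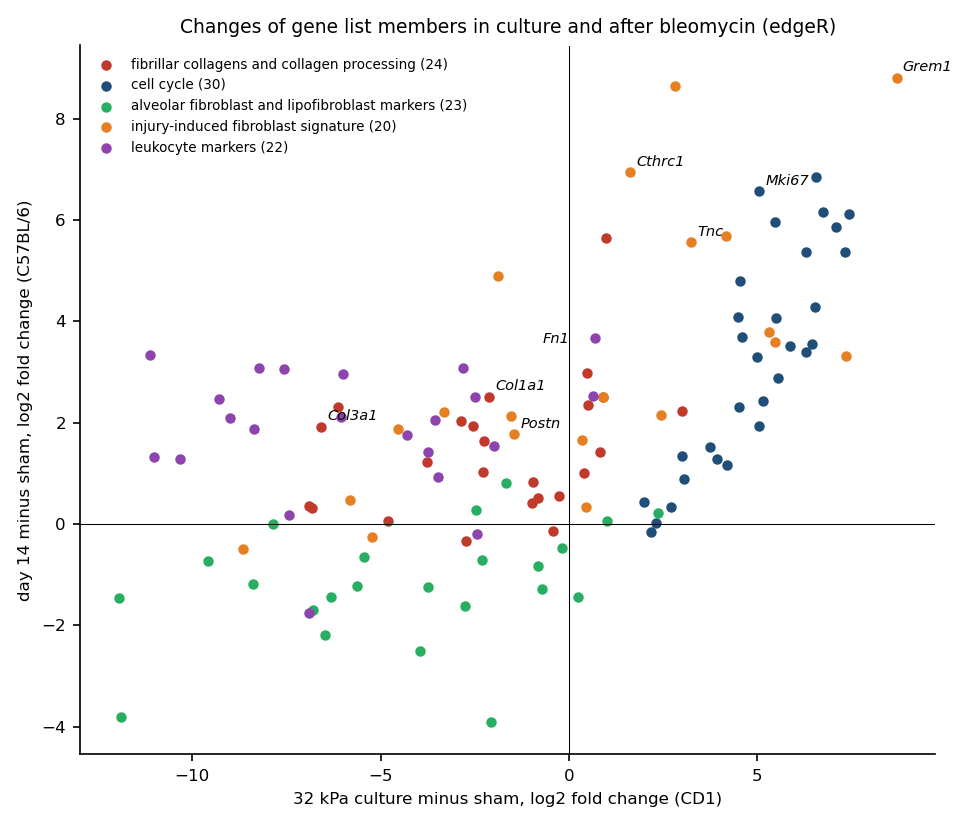
Change of genes of 5 lists on 32 kPa against sham in CD1 (horizontal axis) and at day 14 against sham in C57BL/6 (vertical axis), both as edgeR log2 fold changes, 1 point per gene. Cell cycle genes lie high on both axes, with Mki67 at 5.05 and 6.57, and collagens such as Col1a1 lie at negative culture values (-2.12) and positive injury values (2.52).

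Alveolar markers were lower in both for 14 of 23, adventitial markers for 10 of 20, immediate-early genes for 12 of 20 and lung mesenchyme factors for 8 of 24. The injury signature was higher in both for 10 of 20 and lower in culture but higher at day 14 for 5. Leukocyte markers were lower in culture and higher at day 14 for 13 of 22. Over all genes 1167 were called higher in both (589 for independent lists, odds ratio 4.53, Fisher's exact p = 6.03e-193) and 1053 lower in both (537, 8.27, p = 2.82e-216). Fewer than for independent lists were lower in culture and higher at day 14 (394 against 782) or the reverse (62 against 404). Across genes, which are not independent replicates, Pearson's r was 0.316 for 32 kPa and 0.338 for 0.2 kPa. The edgeR test of the difference placed 3534 of 16211 genes above and 4084 below in culture relative to injury.

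Accessible chromatin was compared through the authors' lists, with log2 folds as deposited and no replicate values. The culture lists asked which regions differed from freshly sorted cells. On 0.2 kPa a region within 1 kb of the Col1a1 TSS (11:94935978-94937586) had a fold of -3.74 (FDR 3.36e-93), and all 7 listed regions of Col1a1 were lower. A region 207968 bp upstream of Tcf21 (10:23027884-23028338) had a fold of -3.66. Regions at the Mki67 TSS (7:135716234-135716868, -2.85) and the Runx1 TSS (16:92697175-92697749, -2.95) were lower although both genes rose in RNA. Among the 3 highest folds was a region nearest to Fut9 (4:25645627-25645899, 5.66), and the lowest fold lay nearest to Bbox1 (2:110273656-110273842, -5.80), both distal.

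The list for 0.2 kPa against sham held 5725 regions higher and 41750 lower. Within 1 kb of a TSS lay 1.80% of the higher and 35.1% of the lower regions. The list for 32 kPa against sham, without a fold limit, held 17328 higher and 41182 lower (15571 and 36797 with an absolute fold of at least 1), with 2.55% and 35.6% within 1 kb of a TSS. On 32 kPa the Col1a1 region was again lower (-3.12), whereas regions near Runx1 (16:92930178-92930395, 4.07), Ankrd1 (19:36128673-36128890, 3.11) and Pparg (6:115316861-115316977, 3.01) were higher. Lower regions still outnumbered higher ones at these genes, 9 against 3 for Runx1, 5 against 4 for Ankrd1 and 4 against 2 for Pparg. The 2 highest folds were distal, nearest to Fut9 (4:25645587-25645928, 6.67) and Rab3b (4:108887527-108887787, 6.37). The lowest lay 713 bp upstream of the Rela TSS (19:5636778-5636878, -6.23), and a region nearest to Kl (5:150979440-150980196, -5.92) was among the 3 lowest. The soft and stiff lists, which share sham libraries, overlapped at 96.9% of the soft regions, with the same direction in 99.99% of pairs.

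On 32 kPa 2551 regions were higher and 7 lower than on 0.2 kPa. Signal to noise or normalization was not tested as the cause. The higher ones had a median fold of 1.09, and 12.1% lay within 1 kb of a TSS. They included regions in introns of Runx1 (16:92608253-92608398, 1.28, FDR 0.00163) and Col1a1 (11:94936804-94936897, 1.02, 0.0055) and an intergenic region 8938 bp upstream of Ankrd1 (19:36128674-36128890, 1.16, 0.00171). Among the 3 highest folds was a region near Il4i1 (7:44833601-44833780, 2.86) and among the 3 lowest one near Slc45a1 (4:150644930-150645108, -2.16), both intronic. Of the listed regions 86.8% overlapped the list of 32 kPa against sham, which shares the 32 kPa libraries. Overlaps higher in both numbered 1760, and 460 were higher than on 0.2 kPa yet lower than in sham. The genes nearest to regions gained on the stiff gel had a median RNA change of -0.05.

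After injury the gains outnumbered the losses. At day 14 against sham 17333 regions were higher and 8185 lower, with median folds of 1.87 and -1.27. Distal regions gained near matrix genes included intergenic ones near Postn (3:54434574-54434911, 5.22, FDR 1.15e-30), Tnc (4:64092871-64093132, 3.53) and Col1a2 (6:4432210-4432464, 3.40). Runx1 gained regions in the intergenic space 26371 bp upstream (16:92852248-92852643, 4.13), in an intron (16:92782541-92782663, 3.98) and at a TSS (16:92825926-92826046, 3.33). Pparg, without an RNA call, had a gained intergenic region (6:115316873-115317205, 5.85). An intergenic region near Acta2 (19:34265521-34266148, -1.02), which rose in RNA, was lower. Among the 3 highest folds was a region in an intron near Abca13 (11:9499753-9500078, 6.75), and the lowest was intergenic near Basp1 (15:25208671-25208951, -3.29).

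**Figure D3:**
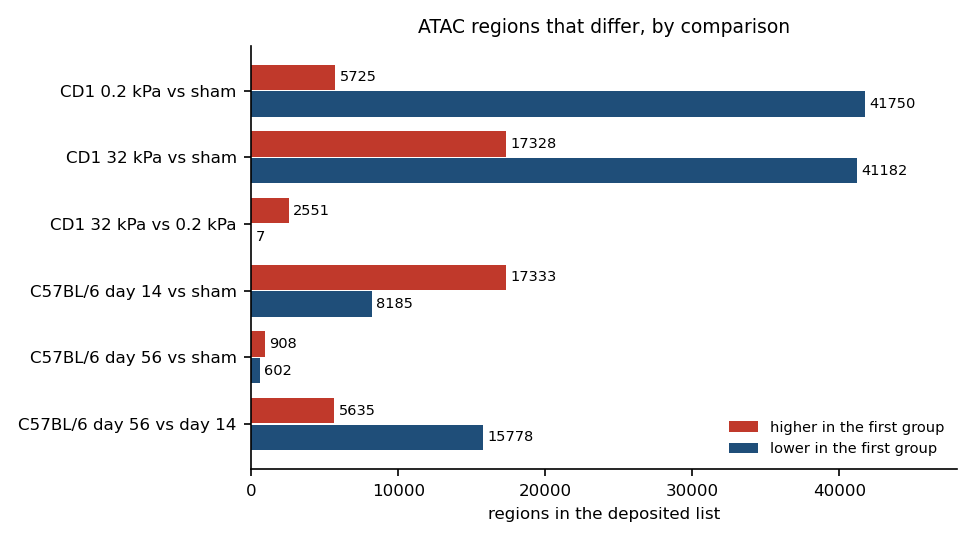
Number of regions with higher and lower accessibility in each of the 6 deposited ATAC lists, as bars from 0 with printed counts. Lower regions exceed higher ones in both culture groups against sham (41750 and 41182 lower), and higher regions exceed lower ones at day 14 (17333 against 8185).

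At day 56 against sham 908 regions were higher and 602 lower. The lowest folds lay on the Y chromosome, near Eif2s3y (Y:1010195-1010687, -7.90) and Uty (Y:1245613-1245912, -7.26), and without X and Y 896 and 592 regions remained. Regions near Tnc (4:63958532-63958983, 1.77) and in an intron of Runx1 (16:92778064-92778710, 1.12) were still higher, and the highest fold lay 9293 bp upstream of Crbn (6:106809258-106809502, 4.76). Of the day 56 regions 62.6% overlapped a day 14 region, with the same direction in 99.8% of pairs, the sham libraries being shared. At day 56 against day 14, 5635 regions were higher and 15778 lower. The Runx1 regions that had opened were lower (16:92852248-92852643, -3.89, and 16:92782541-92782663, -3.93), as were those near Postn (-3.49) and Col1a2 (-2.91), and an intergenic region 50201 bp upstream of Igfbp3 was higher (11:7263692-7264556, 2.96). Of regions gained at day 14, 80.2% overlapped this list and of those lost 45.2%, all but 1 pair in the opposite direction, the day 14 libraries being shared.

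Accessibility and RNA moved together after injury. Of genes with only gained regions at day 14, 649 were called higher and 169 lower in RNA, and of genes with only lost regions 88 and 269 (odds ratio 11.7, Fisher's exact p = 5.13e-71). The odds ratio was 10.3 for day 56 against day 14 (exact p = 2.79e-46) and 1.91 for 0.2 kPa against sham (exact p = 1.3e-07). For 32 kPa against sham it was 1.12 (exact p = 0.188), and 2.13 within 1 kb of a TSS and 2.18 beyond. Between culture and injury, with no shared libraries, 9216 regions of the 32 kPa list (15.8%) overlapped a day 14 region. This held for 34.4% of higher and 7.89% of lower ones. Of the pairs 94.0% had the same direction, 5973 higher in both.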

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

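Of the tests below, those of a swap, of 32 kPa replicate 3 as a soft-gel sample, of regions lost near TSSs, of carried-over leukocytes and of a lower mesenchymal share were chosen after the result was seen. The remaining tests and the splits were written before their results were seen.

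Among the 45 groups of 4 libraries examined, 2 held a library far from the other 3, and chance gives about 1 in 20 such groups. Postn in C57BL/6 day 56 replicate 4 stood at 18304.9 rescaled reads, against 8522 to 9460.0 in the other 3, a gap of 0.904 of the range. Tcf21 in C57BL/6 day 14 replicate 1 stood at 3954.53, against 2325 to 2470.5, a gap of 0.911 of the range.

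Replicates 1 and 2 of 32 kPa lay apart from replicate 3 in RNA. On an axis over 13614 genes from the mean of the 0.2 kPa libraries (0; for each of these, of the other 0.2 kPa libraries) to that of 32 kPa replicates 1 and 2 (1), the highest 0.2 kPa library stood at 0.279, far from the partner that a swap of labels would need. The difference of 32 kPa replicates 1 and 2 from the 0.2 kPa libraries correlated across genes, which are not independent replicates, with that between low-detection and other C57BL/6 sham libraries at r = 0.0872 (0.0720 to 0.102), too weak to tell whether library quality was shared. Replicates 1 and 2 had Rn45s at 1.499% and 1.86% of reads, entries without a symbol at 4.31% and 4.77% (3.03% in replicate 3) and the fewest genes detected in CD1, so a difference in quality stays open. Whether replicate 3 was a soft-gel sample or did not meet the stiffer gel cannot be told: its position, -0.0778, lies near but below those of the 0.2 kPa libraries (-0.0450, 0.0333 and 0.279).

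In culture 35.1% and 35.6% of lost regions lay within 1 kb of a TSS. Genes that rose in RNA had such a lost region in 68.0% of cases on 0.2 kPa and genes of like sham level that fell in 62.6%, a ratio of 1.09, and on 32 kPa the shares were 67.7% and 62.2%, again a ratio of 1.09. Cell cycle genes, all higher in RNA, had a lost region for 28 of 30 members and adventitial markers, nearly all lower, for 18 of 20. These ratios argue against a closing of promoters together with lower expression as the cause. A difference in signal to noise or normalization of the ATAC libraries could give such ratios, and a change of chromatin across the genome, for which no biological test was made, stays open.

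Leukocyte markers and Spp1 rose at day 14 in cells sorted as CD45-negative. Of the measured leukocyte list 95.5% of members (21 of 22) lay above 0, as leukocytes carried past the CD45 gate could give. The leukocyte median exceeded the higher of the epithelial and endothelial medians by 1.97 log2 units, which argues against a lower share of mesenchymal cells alone. Within groups, over 12 libraries, Spp1 and the leukocyte list had a Pearson r of 0.136 (-0.540 to 0.705, permutation p = 0.645) and a Spearman rho of 0.189 (permutation p = 0.492), and r was 0.0369 without the 2 farthest libraries, so their relation cannot be told. At day 14 Spp1 stood at 10489.5 CPM, Lyz2 at 1056 ± 652 against 127 in sham and Ptprc, which encodes CD45, at 21.6 ± 10.4 against 7.41 CPM (SD, n = 4). Expression of these genes by the mesenchymal cells themselves was not tested.

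Other splits of the libraries were run for each count of genes. For day 14 against sham 1 of 35 splits, the real one, reached 3359 genes and the highest other had 0. This share is under 0.05 among these libraries, which may be technical replicates. The same held for day 56 against day 14, with 1 of 35, 2996 genes and 0. For day 56 against sham 6 of 35 splits reached the real count of 1, so chance was not excluded. The highest other there had 668 genes and set sham replicates 1 and 2 with day 56 replicates 2 and 3, the 4 libraries with the fewest genes detected, against the rest, which points to a structure of the samples other than the groups. With 10 splits the CD1 comparisons are too few for a share under 0.05: 0.2 kPa against sham had 13490 genes in 1 split and 0 in the highest other, and 32 kPa against sham 13957 and 0. For 32 kPa against 0.2 kPa all 10 splits reached the real count of 0, and the highest had 457, with 0.2 kPa replicates 1 and 2 beside 32 kPa replicate 3. For the difference between the culture and injury changes, refitted on only those 4 groups, 2 of 40 drawn splits reached the real 7916 genes and the highest other had 8358. The 3 other drawn splits that kept 32 kPa and sham apart, and so held the whole culture change, gave 6981 to 8358, and those that mixed them at most 24, so this count does not tell whether chance could be excluded.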

How the results depend on the processing

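The settings chosen after seeing the data were those listed above. Of gene counts 198 stayed within 1.5 times the main count and 54 moved, and of named genes 10408 values kept direction and side of the threshold, 438 lost and 59 gained the call and 23 moved. For lists the numbers were 625, 126, 19 and 13, which leave out the list tests without 32 kPa replicate 3. Those, for 32 kPa against 0.2 kPa, ended the calls of 5 of 10 lists, and list tests were not run without any other single library. The cause of each change was not tested unless fewer genes or samples entered by construction.

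For 32 kPa against 0.2 kPa, with 0 genes in limma, DESeq2 called 2 higher and 37 lower, library weights 2399 and 2261, and the counts lower were 1 with edgeR and TMM, RLE factors, a mean CPM of at least 1 or a pseudocount of 5, 2 with no filter and 5 with total counts. For day 14 against sham the counts higher and lower were 1327 and 819 with an absolute log2 fold change of at least 1, 1069 and 697 at an adjusted p under 0.01, 3890.0 and 3502 with library weights, 3036 and 2247 without the 4 libraries with the fewest genes detected, and 3 and 0 with only Xist libraries, where sham had 1 library and the spread came from the other groups, so this is no test of the day 14 change. For day 56 against sham they were 59 and 28 with DESeq2, 9 and 3 with no filter, 42 and 18 with library weights, 1 and 0 without the 4 libraries and 7 and 2 with a term for them. A pseudocount of 5 gave 10 higher, the values as deposited 4 lower, and 0 were lower in a fit of only the 2 groups, at an adjusted p under 0.01, without trend, with the Xist or Y term and with only Xist libraries, again with 1 sham.

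For day 56 against day 14 the counts were 706 and 1183 with an absolute log2 fold change of at least 1, 545 and 842 at an adjusted p under 0.01, 777 and 3035 as deposited, 2181 and 3001 with library weights, 1924 and 2821 without the 4 libraries, 730.0 and 1193 with the Xist or Y term and 118 and 230.0 with only Xist libraries. DESeq2 gave 1812 higher and edgeR with total counts 1106 lower. With an estimated correlation 0 lists passed on 0.2 kPa, on 32 kPa, between them and at day 56 against sham, 4 at day 14 and 5 for day 56 against day 14. Fry called 0 lists between the gels and 2 at day 56 against sham. Of genes higher and lower at day 14, 99.7% and 99.3% pointed back with no threshold, and 73.5% of higher genes were called back among those of at least 1 log2 unit.

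Without single libraries the counts higher and lower ranged over 5556 to 6026 and 6807 to 7304 (0.2 kPa against sham), 5829 to 6282 and 7287 to 7874 (32 kPa against sham), 0 to 479 and 0 to 623 (32 kPa against 0.2 kPa), 1339 to 1928 and 909 to 1379 (day 14), 0 to 2 and 0 to 1 (day 56 against sham) and 753 to 1385 and 1109 to 1961 (day 56 against day 14). The ends at 479 and 623 came without 32 kPa replicate 3, those at 1339, 753 and 1109 without day 14 replicate 2, and 781 higher at day 56 against day 14 without day 14 replicate 3. Named genes lost their call without some single library for 15 of 114 at day 14, 22 of 112 for day 56 against day 14, 1 of 1 at day 56 and 1 each of 130 and 129 on 0.2 and 32 kPa.

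With the replicate block, 0 genes were lower at day 56 against sham in limma. The block ended the day 14 call of the contractile list (0.0571). Deviations from group means correlated at -0.543 to 0.356 between same-numbered libraries. Other pairs were not compared, so pairing cannot be told.

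With an absolute ATAC fold of at least 2 the regions higher and lower were 11348 and 21935 (32 kPa against sham), 9 and 4 (32 kPa against 0.2 kPa), 7803 and 361 (day 14), 59 and 57 (day 56 against sham) and 99 and 6015 (day 56 against day 14). At an FDR under 0.001 they were 371 and 0 between the gels and 496 and 167 at day 56 against sham, and at an FDR under 0.01 the lower ones were 0 and 355. With a reciprocal overlap of 50% the overlapping shares were 95.3% (soft and stiff), 18.1% and 76.1% (32 kPa against 0.2 kPa with the soft and stiff lists), 2.97% and 67.7% (day 14 with day 56 against sham and against day 14), 15.3% (both day 56 lists, 50.6% in the same direction) and 12.2%, 9.31% and 13.8% (the 32 kPa, 0.2 kPa and gel lists with day 14). The odds ratio of ATAC and RNA directions on 32 kPa, 1.12, was 2.13 within 1 kb of a TSS, 2.18 beyond and 1.27 for genes of at least 1 log2 unit.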

Other observations

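The motif search, chosen after seeing the data, counted short consensus sequences in distal regions, with Mantel-Haenszel odds ratios over groups of GC content and, where given, 95% intervals. At day 14, 41.0% of gained and 4.88% of lost regions held the AP-1 site bound by Fos and Jun proteins (odds ratio 13.6), and 30.6% and 12.003% held the RUNX site (3.23). NF-kB sites were in 5.16% and 1.77% (2.94). The E-box CAGCTG, in 15.9% and 32.1% (0.374), and CATCTG, in 18.7% and 30.4% (0.522), lay more often in lost regions. At day 56 against sham RUNX sites were in 32.3% of higher and 11.7% of lower regions (3.70, 2.74 to 5.00), whereas AP-1 gave an odds ratio of 1.07 (0.794 to 1.43). The site of steroid receptors was in 0.225% and 8.75% (0.0352).

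In culture AP-1 sites were in 52.8% of gained and 12.9% of lost regions on 0.2 kPa (6.80) and in 50.1% and 12.6% on 32 kPa (6.46). TEAD sites, bound by the partners of YAP and TAZ, had odds ratios of 2.19 and 2.02 and RUNX sites 2.25 and 1.97. Sites of the insulator protein CTCF were in 0.0534% of gained and 6.51% of lost regions on 0.2 kPa (0.00815). Of regions higher on 32 kPa than on 0.2 kPa, those that were also higher than in sham held NF-kB sites in 3.13%, against 2.06% of other regions higher on 32 kPa than in sham (1.71, 1.27 to 2.30). CTCF (0.315, 0.0439 to 2.26) and TEAD sites (0.904, 0.805 to 1.01) had intervals that include 1. With the regions not higher than in sham left in, the CTCF odds ratio was 4.49, so that excess lay outside the regions gained over sham.

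Within C57BL/6 groups, libraries with Xist and libraries with Y genes differed in 6 genes past 0.05 in limma, all 6 on X or Y, and 476 genes on other chromosomes (2.32%) had an unadjusted p under 0.05.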
